A study of Mus musculus with 12 samples.

How the data were processed

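RNA sequencing counts were analysed from 12 libraries of mouse bone marrow-derived macrophages (BMDM), cells grown from bone marrow in M-CSF, the growth factor that drives precursors into macrophages. The cultures held 10 ng/ml M-CSF in DMEM with 10% serum and 1% penicillin and streptomycin, and the donors were 8 weeks old. The 4 groups cross a genotype with a treatment and hold 3 libraries each. The genotypes are Hdac3f/f, in which the Hdac3 gene carries loxP sites (is floxed) but no recombinase is present, and Lyz2-Cre-Hdac3f/f, in which Cre recombinase made from the Lyz2 locus of myeloid cells acts on the floxed gene. The treatment is 500 ng/ml lipopolysaccharide (LPS), the bacterial cell wall component sensed by Toll-like receptor 4, for 4 h, or none. The labels give total RNA extracted with TRIzol as the material and do not say whether the replicates of a group are separate animals, so every p-value here measures the spread between these libraries only.

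The table deposited by the authors holds 54532 genes with coordinates. Its values per library are counts and FPKM, both made by the authors, whose notes name TopHat2 and the mouse build mm10 without a version, a counting tool or an annotation release. The deposited counts are whole numbers that sum to between 16553432 and 18706990 per library. The deposited FPKM values equal the count divided by the deposited gene length in kilobases and by a library size. That library size was not the library's own total: it was the DESeq2 size factor times the same constant in each library, 17802100, and ran from 12524000 to 23885000. The authors also deposited log2 fold changes for the 2 comparisons between genotypes, with a raw p-value and an adjusted p-value for each; the test behind the deposited p-values (p_value) is not named by the authors. Their log2 ratios place Hdac3f/f over Lyz2-Cre-Hdac3f/f, so their sign is opposite to the one used here. Of 54495 gene identifiers also present in the GENCODE M21 annotation, 53585 (98.3%) had the same chromosome, start and end there.

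Counts were the values used throughout. Genes were kept by filterByExpr of edgeR 4.0.16 with the 4 groups, which left 14286 tested genes, and libraries were scaled by TMM, with factors between 0.716 and 1.26. Levels are CPM of the TMM-scaled library size, computed by edgeR, as mean and SD over n = 3 libraries. One quasi-likelihood model with a coefficient per group (edgeR, glmQLFit and glmQLFTest) gave 5 contrasts: the LPS response in each genotype, the difference between genotypes without and with LPS, and the interaction, which is the LPS response in Lyz2-Cre-Hdac3f/f minus that in Hdac3f/f. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05 over all tested genes. Fold changes are log2 values with their standard error (SE), and each group has n = 3. For a gene with 0 counts in a whole group a bound was computed with a floor of 3 counts over the group, and for a gene with 1 to 3 counts in a group the ratio of summed counts was given with its exact 95% interval. Both cover counting error only. In a single library the 3 counts that a count of 0 allows correspond to between 0.160 and 0.181 CPM of the unscaled total.

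To ask whether the interaction leaned one way over LPS-regulated genes, genes were sorted by the mean of the LPS responses in both genotypes (adjusted p under 0.05 and log2 fold change above 1 or below -1). That mean and the interaction are uncorrelated where the spread is equal in all groups, which is only approximate here, as the LPS-treated Hdac3f/f libraries differed more among themselves than the LPS-treated Lyz2-Cre libraries. Lists of genes were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, and p-values were adjusted over lists and contrasts together. Of 26 lists, 25 had at least 5 tested members. They cover inflammatory cytokines, interferon response, feedback regulators of NF-kB, immediate early genes, alternative activation, inflammasome, eicosanoids, lipid genes of LXR and PPAR, oxidative phosphorylation, fatty acid oxidation, glycolysis and hypoxia, cholesterol synthesis, proliferation, p53 targets, HDAC and corepressor subunits, endoplasmic reticulum stress, antigen presentation, NRF2 targets, macrophage identity, osteoclast genes, and markers of neutrophils, lymphocytes, dendritic cells, erythroid cells, mast cells and basophils, and stromal cells. Each list also has a count of called members with p-values adjusted over the list alone. The lists, contrasts, tests, thresholds, the rule for named genes and most alternatives were chosen before the data were examined.

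Named genes follow that rule. Hdac3 was always taken. Each 2-group contrast gave the 7 largest rises and the 7 largest falls among called genes with at least 5 CPM in the higher group, with every library of 1 group above every library of the other, and with symbols that are not clone or predicted names. The interaction gave the 12 genes of lowest p at the same minimum level. Up to 4 members of lowest p were taken from each list, with any exception a sentence needs. A gene named outside this rule is said to be chosen after its values were seen.

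The alternatives were DESeq2 size factors, library totals alone and upper-quartile scaling; no filter or a filter of 1 CPM in 6 libraries; DESeq2 1.42.0, limma-voom and limma on log2 FPKM with a pseudocount of 1; a term for replicate number; a fit of only the 2 groups compared; an added requirement of an absolute log2 fold change above 1, or an adjusted p under 0.01; a mean LPS response above 2 on the log2 scale; camera with an estimated correlation, and fry; and each library left out in turn. Chosen after seeing the data were offsets for GC content and gene length (loess in each library, span 0.5, degree 2), a covariate holding each library's mean log2 CPM of stromal markers (the stromal score), and a fit without 2 doubted libraries. GC content came from the mm10 sequence for 14273 (99.9%) of the tested genes. Groupings of the libraries other than the real ones were fitted too, with 100 drawn where there were more. All fits ran in R 4.3.3.

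The procedure was tested on simulated data made from these counts with known changes placed in 200 of 14286 genes. For the interaction these were drawn only from genes above a minimum level in every group. All 5 real contrasts called far more genes. Apart from the GC trend below, each simulated gene was also drawn independently, without shifts shared by many genes. The rates below may therefore not carry over to any of the real contrasts. At a 2-fold change 42.0% to 55.9% of changed genes were called over the 5 contrasts, at a 4-fold change 76.5% to 91.4%, and 2.94% to 8.20% of calls were false. With a trend on GC content added to the simulated counts of the genotype comparison with LPS, 12.5% of calls were false without the offsets and 5.77% with them. Alternatives for a table without counts were not needed and were not run. No sample column was left out.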

Results

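The data are counts of RNA sequencing reads per gene from 12 libraries of mouse bone marrow-derived macrophages. There were 3 libraries each of untreated Hdac3f/f cells, Hdac3f/f cells given LPS, untreated Lyz2-Cre-Hdac3f/f cells (called Lyz2-Cre below) and Lyz2-Cre cells given LPS. Totals per library ran from 16553432 to 18706990 counts, and between 18159 and 21296 genes had at least 1 count in a library. In a principal component analysis of the tested genes the first axis (64.0% of the variance) separated all LPS-treated from all untreated libraries, and the second (18.0%) separated all libraries of the 2 genotypes. Pairs of replicates differed by more than counting noise, with a chi-square per gene of 8.65 to 51.4, where counting noise alone gives about 1. Log2 fold changes are given ± SE and levels as mean CPM ± SD, with n = 3 libraries in each group. For the genes given as the largest rises and falls of a 2-group comparison, all 3 libraries of 1 group lay above all 3 of the other.

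Whether the targeted gene differed between the genotypes was asked first. Hdac3 (ENSMUSG00000024454, mm10 chromosome 18, 37935844 to 37954988) encodes histone deacetylase 3, the catalytic subunit of the NCoR and SMRT corepressor complexes. Its level was 38.4 ± 1.86 CPM (SD, n = 3) in untreated Hdac3f/f cells and 34.9 ± 1.75 CPM (SD, n = 3) in untreated Lyz2-Cre cells. With LPS the levels were 39.5 ± 1.08 and 37.1 ± 2.37 CPM (SD, n = 3). The log2 fold change between genotypes was -0.14 ± 0.09 without LPS (adjusted p = 0.352) and -0.09 ± 0.09 with LPS (adjusted p = 0.473), and Hdac3 was not called in either. The count covers the whole gene, and the floxed exons cannot be separated from the rest, so it does not measure how far the gene was recombined. With library totals alone the value with LPS was 0.17, on the other side of 0.

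Lyz2 (ENSMUSG00000069516, mm10 chromosome 10, 117277331 to 117282321), which encodes lysozyme and carries the Cre insertion in the Lyz2-Cre genotype, was named after its values were seen. Its level was 10493 ± 1365 CPM in untreated and 11372 ± 926 CPM in LPS-treated Hdac3f/f cells. In the 3 untreated Lyz2-Cre libraries it was 31.0, 5181 and 5637 CPM, and in Lyz2-Cre cells with LPS it was 6689 ± 903 CPM. Leaving aside the library with 31.0 CPM, the other 5 Lyz2-Cre libraries held 49.4% to 68.0% of the Hdac3f/f mean at the same treatment. The neighbouring paralog Lyz1, also chosen after its values were seen, was higher in Lyz2-Cre cells, at 46.6 ± 16.2 against 18.69 ± 1.96 CPM without LPS.

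**Figure D1:**
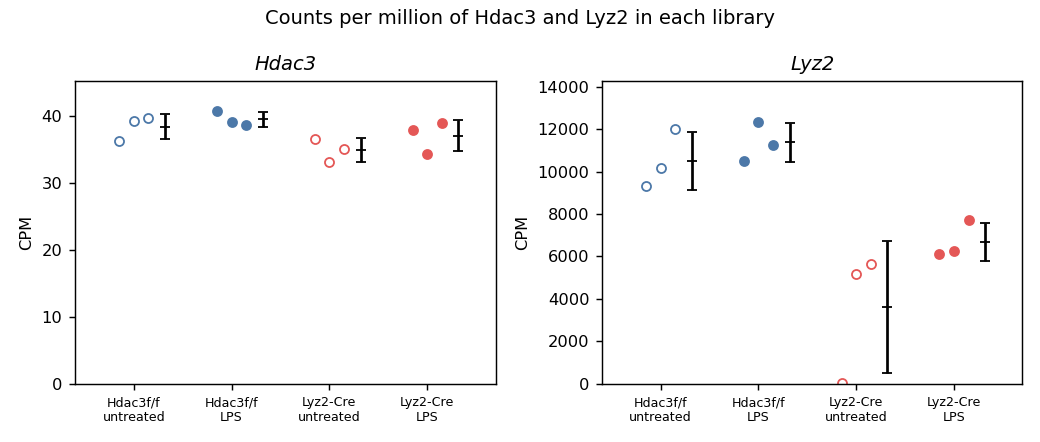
CPM of Hdac3 (left) and Lyz2 (right), linear axes; circles are single libraries (open, untreated; filled, LPS; blue, Hdac3f/f; red, Lyz2-Cre-Hdac3f/f), and bars beside them are the mean and SD of 3 libraries. Hdac3 means lie between 34.9 and 39.5 CPM, and 1 untreated Lyz2-Cre library has 31.0 CPM of Lyz2.

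The first comparison asked how Hdac3f/f macrophages respond to 4 h of LPS. All tested cytokine, interferon response and NF-kB feedback genes rose, as did 19 of 21 glycolysis and hypoxia genes and 11 of 12 NRF2 targets, while 21 of 25 proliferation genes and 14 of 22 fatty acid oxidation genes fell. The cytokine and NF-kB feedback lists were called with an estimated correlation too; the other 5 were not (adjusted p from 0.147 to 0.282 with an estimated correlation). Il1b, the precursor of interleukin 1 beta, rose from 0.896 ± 0.438 to 2298 ± 238 CPM, a log2 fold change of 11.29 ± 0.48. Nos2, the inducible nitric oxide synthase, rose from 0.748 ± 0.571 to 2394 ± 877 CPM (log2 fold change 11.59 ± 0.49). Csf3, which encodes granulocyte colony-stimulating factor, had 0 counts in the 3 untreated libraries and 151 ± 39.2 CPM with LPS, at least 3157-fold higher with the 0 set to the floor of 3 counts over the group. Arhgap19, a GTPase-activating protein, fell from 298 ± 27.2 to 4.24 ± 0.405 CPM (log2 fold change -6.13 ± 0.14).

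Further genes among the largest rises were the chemokine gene Cxcl11 (log2 fold change 9.77 ± 0.53) and 3 genes with 1 to 3 counts in all untreated libraries together. For these the ratio of counts was 2210 (95% interval 396 to 87369) for U90926, 1136 (388 to 5514) for Ifng, which encodes interferon gamma, and 1094 (302 to 9040) for Shisa3. The other large falls were Zdhhc14 (-6.24 ± 0.21), Nat8l, the enzyme that makes N-acetylaspartate (-6.39 ± 0.31), Tmem144 (-5.94 ± 0.47) and the pseudogene Nlrp1c-ps (-5.80 ± 1.20). Abcd2, a peroxisomal fatty acid transporter, was lower by a ratio of 142 (95% interval 38.9 to 1172) and Chp2 by 79.0 (26.8 to 385).

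All 22 tested inflammatory cytokine genes rose, with a median log2 fold change of 7.23 (adjusted p = 1.2e-16, camera; 22 adjusted over the list alone). Csf3 lies above this median at its bound too. The members of lowest p were Il6 (8.54), Tnf (7.95), Il27 (8.32) and Il1a (7.24). All 21 genes of the NF-kB feedback list rose (median 4.00, adjusted p = 3.5e-17, camera, and 21 adjusted over the list alone). Among them were Traf1 (5.57), Nfkbia (5.36), Tnfaip3 (5.18) and Nfkbie (4.48). Besides inhibitors of the pathway, the list holds Nfkb1, Nfkb2, Rel and Relb, which encode NF-kB subunits themselves. The cytokine and NF-kB feedback lists were called by camera with an estimated correlation too (adjusted p = 0.0285 for both lists). All 30 interferon response genes rose (median 3.48, adjusted p = 6.7e-17; 30 adjusted over the list alone), including Cxcl10 (9.42), Cmpk2 (5.58), Usp18 (3.93) and Igtp (3.60). Their call was lost with an adjusted p = 0.185 with an estimated correlation.

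Of 14 immediate early genes 10 rose, 1 fell and 3 were not called, and the counts were the same adjusted over the list alone (median 1.27, adjusted p = 0.00217; adjusted p = 0.315 with an estimated correlation). Maff (4.55), Junb (3.85), Ier2 (3.61) and Nr4a1 (2.94) rose, and Klf2, a transcription factor that restrains macrophage activation, fell (-1.18). Of 15 inflammasome genes 10 rose and 3 fell, or 11 and 3 adjusted over the list alone (median 2.23, adjusted p = 3.0e-04; adjusted p = 0.153 with an estimated correlation). Nlrp3, the sensor itself, rose by 5.28 and Casp4 by 3.79, while Nlrp1b (-4.68), Nek7 (-0.79) and Txnip (-0.38) fell. Of 18 antigen presentation genes 14 rose and 1 fell, or 15 and 1 adjusted over the list alone (median 0.90, adjusted p = 1.0e-04; adjusted p = 0.315 with an estimated correlation), with Cd40 (6.25), Nlrc5 (2.70), Tap2 (2.54) and Tap1 (2.12) rising. Ciita, the master regulator of MHC class II, fell (-0.60).

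Some metabolic lists moved as well. Oxidative phosphorylation (adjusted p = 0.740, camera) and the lipid genes of LXR and PPAR (adjusted p = 0.899, camera) were not called. Of 21 glycolysis and hypoxia genes 19 rose and 2 were not called, with the same counts adjusted over the list alone (median 1.40, adjusted p = 7.2e-08; adjusted p = 0.147 with an estimated correlation), led by Slc2a1, the glucose transporter (3.89), Pfkfb3 (3.09), Hk2 (2.16) and Pfkl (2.13). Of 12 NRF2 targets 11 rose and 1, Gclc, fell by 0.35 on the log2 scale, the same adjusted over the list alone (median 1.41, adjusted p = 3.3e-05; adjusted p = 0.162 with an estimated correlation). Slc7a11, the cystine transporter, rose by 4.41, Gsr by 2.79 and Txnrd1 by 2.27. Of 20 cholesterol synthesis genes 17 rose and 1 fell, the same adjusted over the list alone (median 1.17, adjusted p = 5.1e-05; adjusted p = 0.404 with an estimated correlation). Fdft1 (2.18) and Insig1 (1.54) rose and Dhcr7, the last enzyme of the pathway, fell (-1.85). Of 22 fatty acid oxidation genes 14 fell and 3 rose (median -0.89, adjusted p = 0.00475; adjusted p = 0.147 with an estimated correlation). Hadh (-2.75), Acadm (-2.14) and Cpt1a, the carnitine transferase that admits fatty acids to mitochondria (-1.32), fell, while Acsl1, which activates long-chain fatty acids, rose (5.04). Of 25 proliferation genes 21 fell, 1 rose and 3 were not called, the same adjusted over the list alone (median -1.19, adjusted p = 4.3e-05; adjusted p = 0.282 with an estimated correlation), with Mcm2 (-1.93), Mcm4 (-1.77), Rrm2 (-1.50) and Mcm3 (-1.39) falling and the cyclin gene Ccne1 rising (1.59).

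In all, edgeR called 8584 of 14286 genes in this response, of which 3993 rose and 4591 fell, and 2247 rose and 2804 fell by more than 1 on the log2 scale. The scale matters for the balance: TMM factors averaged 1.19 in untreated and 0.763 in LPS-treated Hdac3f/f libraries. With library totals alone the median of all tested genes was -0.72 and 2086 rose and 8242 fell, so all changes here are relative to the TMM scale, where that median was -0.08.

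The same question in Lyz2-Cre cells gave 7564 called genes, 3606 rising and 3958 falling, of which 1728 rose and 2210 fell by more than 1 on the log2 scale. Il1b rose from 2.63 ± 1.85 to 2403 ± 105 CPM (log2 fold change 9.85 ± 0.44), and Ptgs2, the cyclooxygenase of prostaglandin synthesis, from 1.82 ± 0.0636 to 1630 ± 262 CPM (9.80 ± 0.52). Serpinb2, the plasminogen activator inhibitor 2, rose from 3.17 ± 0.753 to 1353 ± 125 CPM (8.73 ± 0.42), against 252 ± 55.4 CPM in Hdac3f/f cells with LPS. Cxcl1, a neutrophil chemokine, rose to 150 ± 58.6 CPM (8.67 ± 0.47), against 54.2 ± 14.2 CPM in Hdac3f/f cells with LPS.

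Ifng rose by 9.10 ± 0.50, and for genes with few untreated counts the ratio was 6140 (95% interval 1102 to 242586) for Csf3 and 1999 (553 to 16512) for U90926. The largest falls were Chp2 (-6.64 ± 0.55), Arhgap19 (-5.92 ± 0.14), Zdhhc14 (-5.67 ± 0.19), Abcg3 (-5.64 ± 0.59), the circadian transcription factor gene Dbp (-5.26 ± 0.22), Lpar5 (-5.18 ± 0.26) and Rnf144b (-5.16 ± 0.24). Across all tested genes the responses of the 2 genotypes had a Pearson r of 0.872, a correlation across genes, which are not independent replicates. Of the genes that rose, 3052 rose in both genotypes against 1008 for independent sets, and 3302 fell in both against 1272. Opposite calls were made for 36 of the genes that rose and 20 of those that fell in Hdac3f/f cells.

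All 22 cytokine genes rose in Lyz2-Cre cells too (median 6.59, adjusted p = 6.6e-18; 22 adjusted over the list alone), among them Il6 (7.37), Il1a (7.04), Tnf (6.93) and Il27 (5.41). All 21 NF-kB feedback genes rose (median 3.19, adjusted p = 5.2e-19; 21 adjusted over the list alone), with Tnfaip3 (4.63), Nfkbia (4.49), Tnip3 (4.34) and Traf1 (4.31). With an estimated correlation both lists had an adjusted p = 0.0285. Of the 30 interferon response genes 28 rose (median 2.06, adjusted p = 1.4e-13; adjusted p = 0.243 with an estimated correlation), with Cxcl10 (7.32), Gbp5 (5.16), Igtp (2.56) and Usp18 (2.51), and Ifnb1 (0.54) and Oas2 (0.43) were not called. Of 12 NRF2 targets 12 rose (median 1.57, adjusted p = 1.1e-07; adjusted p = 0.147 with an estimated correlation), with Slc7a11 at 4.28 and Gsr at 2.91.

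Of the 21 glycolysis and hypoxia genes 18 rose (median 1.23, adjusted p = 6.0e-09; adjusted p = 0.147 with an estimated correlation), with Slc2a1 at 3.67 and the lactate exporter gene Slc16a3 at 3.25. Of the 20 cholesterol synthesis genes 17 rose and 1 fell, or 18 and 1 adjusted over the list alone (median 1.29, adjusted p = 6.7e-06; adjusted p = 0.382 with an estimated correlation), with Fdft1 at 2.04, Insig1 at 1.73 and Dhcr7 at -1.87. Of 14 immediate early genes 9 rose and 2 fell (median 1.05, adjusted p = 0.00206; adjusted p = 0.315 with an estimated correlation). Of 15 inflammasome genes 10 rose and 3 fell (median 1.79, adjusted p = 4.7e-04; adjusted p = 0.155 with an estimated correlation). Of 22 fatty acid oxidation genes 14 fell and 2 rose, or 15 and 4 adjusted over the list alone (median -0.59, adjusted p = 0.0104; adjusted p = 0.147 with an estimated correlation), with Hadh at -2.67 and Acaa2 at -2.31, and Acsl1 at 4.08.

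Of the 25 proliferation genes 13 fell, 2 rose and 10 were not called, or 16 and 3 adjusted over the list alone (median -0.63, adjusted p = 0.0451; adjusted p = 0.547 with an estimated correlation). Mcm2 (-1.20) and Mcm3 (-0.67) fell, and Ccne1 (1.93) and Tyms (0.99) rose. That call was also lost without untreated Lyz2-Cre replicate 3 (adjusted p = 0.0809), without Lyz2-Cre LPS replicate 1 (0.0731) or replicate 2 (0.0781), with DESeq2 size factors (0.0503), with library totals (0.0512) and with offsets for GC content and length (0.0541), and over all its alternatives the adjusted p ran from 0.00700 to 0.547. Antigen presentation genes were not called as a list in Lyz2-Cre cells (8 rose and 3 fell, median 0.33, adjusted p = 0.158), with Cd40 at 4.40 and Ciita at -2.92. With library totals alone the median of all genes in this response was -0.46, with 2109 rising and 6463 falling.

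**Figure D2:**
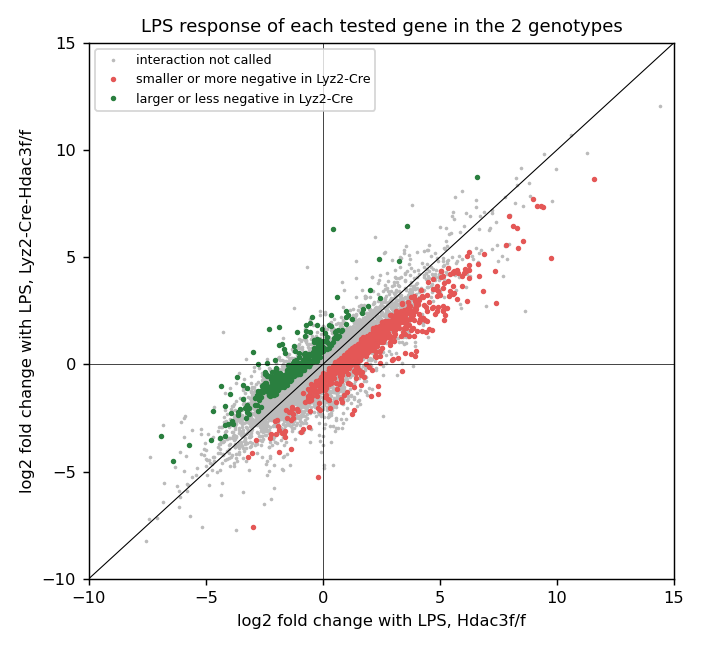
Log2 fold change with LPS of each of the 14286 tested genes in Hdac3f/f (horizontal) and Lyz2-Cre-Hdac3f/f (vertical) cells, with the line of equal response; grey points were not called in the interaction. Among called genes 791 (red) lie below the line and 369 (green) above it.

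Which genes differ between the genotypes in resting cells was asked next. Untreated Lyz2-Cre macrophages had more transcripts of Gdpd3, Mmp9 and 21 of 30 interferon response genes. They had fewer of 16 of 25 proliferation, 10 of 20 cholesterol synthesis and 6 of 12 stromal genes, with 1 stromal gene higher. None of these 4 list calls held with an estimated correlation (adjusted p from 0.147 to 0.404 with an estimated correlation). Gdpd3, a lysophospholipase D, was at 58.3 ± 8.70 CPM against 2.03 ± 0.410 (log2 fold change 4.84 ± 0.30). Mmp9, the gelatinase of matrix breakdown, was at 445 ± 87.6 CPM against 39.1 ± 6.20 (3.51 ± 0.22, adjusted p = 3.8e-06). The list with the lowest adjusted p was interferon response: 21 of 30 genes were higher and none lower, or 25 higher adjusted over the list alone (median 0.71, adjusted p = 8.7e-13; adjusted p = 0.244 with an estimated correlation). Rsad2, the antiviral enzyme viperin, was higher by 1.14 ± 0.20, Gbp3 by 1.22, Usp18 by 0.80 and Stat2 by 0.59.

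Other genes with large rises were the class I-like gene H2-M2 (2.67 ± 0.35), the chemokine gene Ccl8 (2.39 ± 0.32), Il12rb1, a receptor chain for interleukins 12 and 23 (2.35 ± 0.25; 83.9 ± 7.92 against 16.4 ± 4.35 CPM), and the ribosomal protein pseudogenes Rps2-ps10 (3.06 ± 0.27) and Rpl34-ps1 (2.56 ± 0.60). How reads shared with the parent genes of such pseudogenes were assigned is not stated. The call for Rpl34-ps1 was lost in 5 of 27 other settings, among them the fit without untreated Hdac3f/f replicate 2 and the one without untreated Lyz2-Cre replicate 1. Of the 22 cytokine genes 7 were higher and 2 lower, or 10 and 2 adjusted over the list alone (median 1.03, adjusted p = 9.5e-04; adjusted p = 0.268 with an estimated correlation). Cxcl3 (2.92), Nos2 (2.63), Ccl7 (1.36) and Ccl2 (1.11) were higher, and the chemokine genes Ccl4 (-1.23) and Ccl3 (-0.81) were lower. Of 8 mast cell and basophil markers 6 were higher, or 8 adjusted over the list alone (median 0.97, adjusted p = 1.6e-05; adjusted p = 0.244 with an estimated correlation), with Fcer1a at 1.29, Mcpt8 at 1.05, Hdc at 1.02 and Ms4a2 at 0.97.

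Of the 25 proliferation genes 16 were lower and 9 not called, or 19 lower adjusted over the list alone (median -0.71, adjusted p = 3.2e-11; adjusted p = 0.147 with an estimated correlation). Birc5 (-1.23), Tk1 (-1.14), Plk1 (-1.14) and Rrm2 (-0.85) had the lowest p. Of the 20 cholesterol synthesis genes 10 were lower, or 11 lower and 1 higher adjusted over the list alone (median -0.64, adjusted p = 4.2e-07; adjusted p = 0.315 with an estimated correlation), among them Fdft1 (-0.90), Msmo1 (-0.88) and Insig1 (-0.80). Of 14 immediate early genes 4 were lower, or 6 lower and 1 higher adjusted over the list alone (median -0.38, adjusted p = 0.0013; adjusted p = 0.311 with an estimated correlation), namely Myc (-1.17), Egr2 (-0.85), Egr1 (-0.77) and Nr4a1 (-0.63).

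The largest falls included Wisp2 (-4.96 ± 0.82), Loxl1, which crosslinks elastin (-4.28 ± 0.70), the collagen genes Col3a1 (-3.90 ± 0.88) and Col6a1 (-3.85 ± 0.70), and Dkk3 (-3.85 ± 0.84), together with St6galnac2, a sialyltransferase (-4.57 ± 0.45), and Cd300ld5 (-4.36 ± 0.65). Of 12 tested stromal markers 6 were lower, 1 higher and 5 not called, or 9 and 1 adjusted over the list alone (median -2.65, adjusted p = 8.4e-05; adjusted p = 0.404 with an estimated correlation). Col1a2 (-3.52), Col1a1 (-3.47), Pdgfrb (-2.99) and Acta2 (-2.72) were lower, and Pecam1, which endothelial cells also express, was higher (1.33). Libraries of 1 group differed in these genes: the untreated Hdac3f/f libraries had Col1a1 levels of 831, 174 and 283 CPM, and the mean in untreated Lyz2-Cre cells was 38.7 ± 38.4 CPM. The call of the list was lost without the Hdac3f/f library of highest Col1a1 and the Lyz2-Cre library that lacks Lyz2 (median -1.03, adjusted p = 0.128), and with the stromal score as a covariate (median -0.86, adjusted p = 0.484), and over all alternatives the adjusted p ran from 2.7e-07 to 0.484. Col3a1 lost its call in 3 of 27 settings and Dkk3 in 4, the fit without untreated Lyz2-Cre replicate 3 among both.

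In this comparison edgeR called 1684 genes, of which 732 were higher and 952 lower in Lyz2-Cre cells, with 312 and 482 beyond 1 on the log2 scale. The count moved when 1 library was left out. It was 2530 without Hdac3f/f replicate 1, and 793, 779, 905, 948 and 828 without Hdac3f/f replicates 2 and 3 and Lyz2-Cre replicates 1, 2 and 3. Such a fit has fewer libraries in a group, so a lower count does not single out the library left out. Over all genes the fold change had a Spearman correlation of -0.284 with GC content. Ribosomal protein genes held 2.98% to 3.85% of counts in untreated Hdac3f/f and 2.27% to 2.67% in untreated Lyz2-Cre libraries. Mitochondrial genes held 0.824% to 0.989% and 0.670% to 0.773% in the same groups. The authors' own table lists 2336 genes with an adjusted p under 0.05 here, and of the 2313 tested here 1532 were called as well, all in the same direction.

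Which genes differ between the genotypes with LPS was asked in the same way. Lyz2-Cre cells had more transcripts of the integrin genes Itgax and Itgad, Mmp9 and Gdpd3, and fewer of 13 of 18 antigen presentation, 14 of 21 NF-kB feedback, 9 of 14 immediate early and 16 of 30 interferon response genes. None of these 4 list calls held with an estimated correlation (adjusted p from 0.153 to 0.404 with an estimated correlation), and the interferon call was also lost with the stromal score as a covariate. Itgax, which encodes the integrin CD11c, was at 433 ± 13.5 CPM against 35.7 ± 2.02 (log2 fold change 3.60 ± 0.15, adjusted p = 1.2e-07). Mmp9 was at 1638 ± 179 CPM against 208 ± 57.5 (2.98 ± 0.22), and Gdpd3 at 39.5 ± 14.2 against 0.982 ± 0.501 (5.30 ± 0.34). Tnf was lower, at 708 ± 94.2 against 1745 ± 282 CPM (-1.30 ± 0.15), whereas Il1b was at 2403 ± 105 against 2298 ± 238 CPM and was not called (0.06 ± 0.29).

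Further rises were Rps2-ps10 (3.76 ± 0.28), Camk4, a calcium-dependent kinase (2.77 ± 0.34), Itgad, which encodes CD11d (2.58 ± 0.24), and H2-DMb2, a chaperone of MHC class II loading (2.48 ± 0.47). Of 18 antigen presentation genes 13 were lower and none higher, or 15 lower adjusted over the list alone (median -0.91, adjusted p = 6.4e-07; adjusted p = 0.218 with an estimated correlation). Cd40 (-1.63), Ciita (-1.52), H2-DMa (-1.19) and Tap2 (-0.92) were among them. So were the class I genes H2-D1 (-1.25) and H2-K1 (-0.99), chosen after their values were seen. For both, untreated Lyz2-Cre replicate 1 stood apart from its group. H2-D1 was at 7128 CPM there and at 3637 and 3988 CPM in the others, and H2-K1 at 7594 against 4681 and 5258 CPM. Both lie on chromosome 17. Whether sequence variants linked to the genotype add to the values of this list, here or in the interaction, was not tested. Of the 21 NF-kB feedback genes 14 were lower, or 15 lower and 2 higher adjusted over the list alone (median -0.61, adjusted p = 6.9e-06; adjusted p = 0.153 with an estimated correlation), including Dusp2 (-1.84), Zfp36 (-1.41), Traf1 (-1.04) and Nfkbie (-0.98). Of 14 immediate early genes 9 were lower (median -0.70, adjusted p = 1.0e-04; adjusted p = 0.227 with an estimated correlation), with Egr1 at -2.12 and Ier2 at -1.30.

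Of the 30 interferon response genes 16 were lower and 14 not called, the same adjusted over the list alone (median -0.56, adjusted p = 1.3e-06; adjusted p = 0.404 with an estimated correlation), with Cxcl9 (-2.61), Cmpk2 (-1.44), Rsad2 (-1.26) and Oas1a (-0.84). Over all alternatives the adjusted p ran from 8.8e-09 to 0.801. The highest value was found with the stromal score as a covariate (median 0.04), which ended the call, a score that was higher in all Hdac3f/f than in all Lyz2-Cre libraries with LPS. Cytokine genes were not called as a list (3 higher, 7 lower, median -0.38, adjusted p = 0.0915): Ccl4 (-1.83), Il27 (-1.78) and Tnf were lower and the neutrophil chemokine gene Cxcl3 was higher (1.89). Of the 20 cholesterol synthesis genes 13 were lower and 1 higher, or 14 and 1 adjusted over the list alone (median -0.60, adjusted p = 1.1e-04; adjusted p = 0.423 with an estimated correlation). Fdft1 (-1.04), Srebf2 (-0.69) and Insig1 (-0.61) were lower, and Stard4, a sterol carrier, was higher (1.01). Of 19 lipid genes of LXR and PPAR 11 were lower and 2 higher, or 12 and 2 adjusted over the list alone (median -0.45, adjusted p = 0.0125; adjusted p = 0.147 with an estimated correlation, and 0.0566 with GC and length offsets, in a range over alternatives of 2.0e-04 to 0.147). Fabp4 (-1.52) and Nr1h3 (-0.92) were lower, while the scavenger receptor gene Cd36 (0.96) and the cholesterol exporter gene Abca1 (1.06) were higher.

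The stromal list was lower with LPS as well: 9 of 12 genes, or 10 lower and 1 higher adjusted over the list alone (median -3.48, adjusted p = 8.4e-05; adjusted p = 0.404 with an estimated correlation), with Col3a1 at -6.36, Col1a2 at -5.81, Col1a1 at -5.72 and Acta2 at -3.55. Col1a1 was at 726 ± 270 CPM in Hdac3f/f and 13.7 ± 1.41 CPM in Lyz2-Cre cells. With the stromal score itself as a covariate the median was -0.45 and the direction of the test turned (adjusted p = 0.994, the highest of a range from 6.0e-07). The largest falls with LPS included Igfbp5 (-8.17 ± 1.04), Dkk3 (-6.38 ± 1.21) and Alpl (-6.90 ± 0.93), and, as ratios of counts, Wisp2 lower by 301 (95% interval 103 to 1465), Islr by 96.8 (32.7 to 473) and Ssc5d by 92.8 (31.3 to 453). St6galnac2 was at 0.104 ± 0.131 against 33.0 ± 13.4 CPM (-8.27 ± 0.52). Dkk3 lost its call in 1 of 27 settings.

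Of 11 lymphocyte markers 5 were higher, or 6 adjusted over the list alone (median 0.90, adjusted p = 0.0451; adjusted p = 0.546 with an estimated correlation), with Cd3e (1.61), Ncr1 (1.25), Cd3d (1.20) and Cd3g (1.16, from 1.54 ± 0.0580 to 3.44 ± 1.04 CPM). The call was lost without Hdac3f/f LPS replicate 1 (adjusted p = 0.203), without Lyz2-Cre LPS replicate 3 (0.182) and with library totals (0.153), in a range over alternatives of 0.00570 to 0.546. Of 8 mast cell and basophil markers 5 were higher and 1 lower, or 6 and 1 adjusted over the list alone (median 1.08, adjusted p = 0.0194; adjusted p = 0.485 with an estimated correlation). Ms4a2 (1.70), Cpa3 (1.19) and Mcpt8 (0.96) were higher and Hdc, which makes histamine and is also expressed by macrophages, was lower (-1.30). This call was lost without the same libraries (adjusted p = 0.102 and 0.0821), with library totals (0.0528) and with the stromal score covariate (0.204), in a range of 0.00227 to 0.485.

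The genotype comparison with LPS called 4656 genes, 2243 higher and 2413 lower in Lyz2-Cre cells, with 660 and 830 beyond 1 on the log2 scale. The count fell to 2983, 2967, 2798 and 3071 without Hdac3f/f LPS replicates 2 and 3 and Lyz2-Cre LPS replicates 1 and 2, and to 1330 with the stromal score as a covariate, where the untreated comparison called 1358. With library totals alone 4465 genes were higher and 1329 lower, and the median of all genes moved to 0.29. The fold change fell with GC content over all genes (Spearman correlation -0.426). Its median was 0.42 in the fifth of lowest GC content and -0.30 in the fifth of highest. Replicates of 1 group differed in such trends too. Log2 CPM relative to the group mean had Spearman correlations with GC content of -0.514, 0.469 and 0.128 in Hdac3f/f LPS replicates 1, 2 and 3. In Lyz2-Cre LPS replicates 1, 2 and 3 they were -0.212, -0.102 and 0.268. With GC and length offsets 4363 genes were called, of which 3199 were among the 4656. The authors' table lists 3959 genes with an adjusted p under 0.05, of which 3882 were tested here and 3646 called, all in the same direction. Of the genes higher in Lyz2-Cre cells 238 were so both with and without LPS, against 115 for independent sets, and 105 that were higher without LPS were lower with it. For genes lower in both the count was 547 against 161, with 15 opposite.

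**Figure D3:**
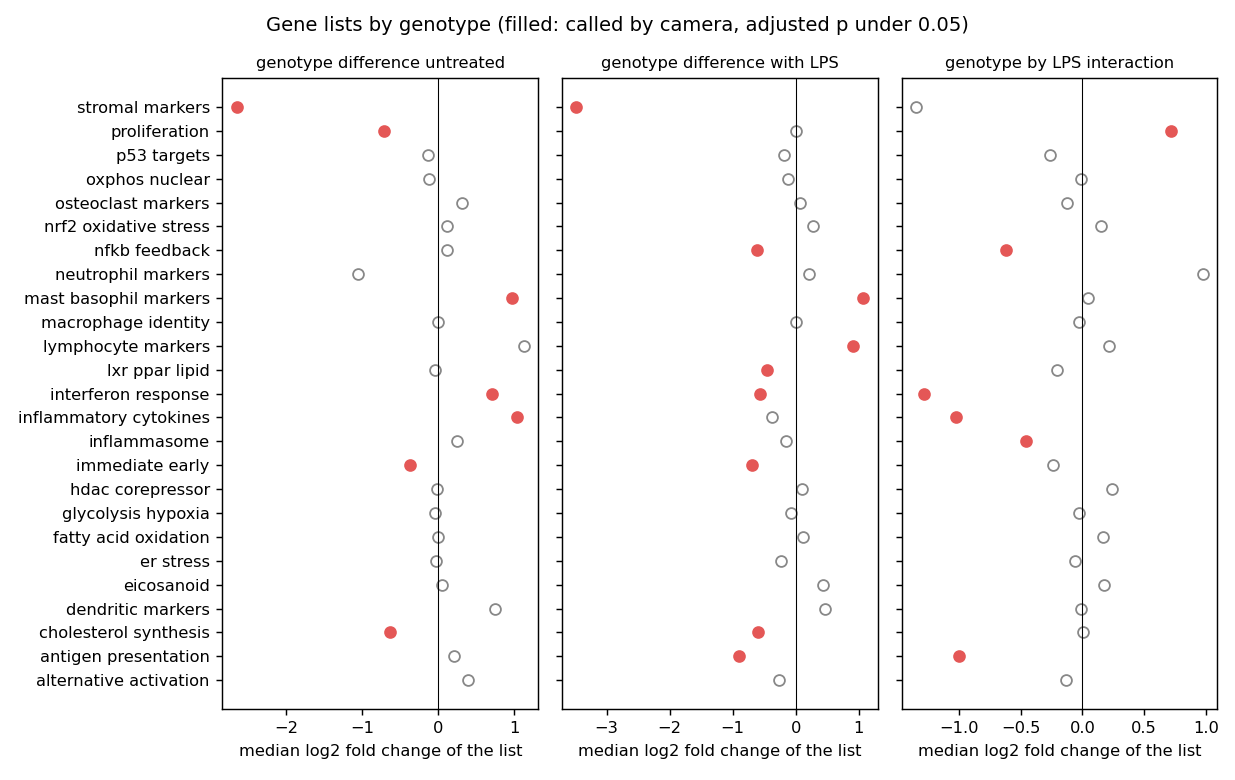
Median log2 fold change (horizontal axes) of each of the 25 tested gene lists for the genotype difference untreated, the genotype difference with LPS and the interaction. Filled red points were called by camera, none of them with an estimated correlation, and open grey points were not called. The interferon response median is 0.71 without LPS, -0.56 with LPS and -1.28 in the interaction.

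The last comparison tested whether the response to LPS itself depends on genotype. It did for 1160 genes: for 791 the log2 fold change with LPS was lower in Lyz2-Cre than in Hdac3f/f cells and for 369 it was higher, with 383 and 172 beyond 1 on the log2 scale. That balance depends on the scale: with library totals alone 448 were negative and 1134 positive, and with upper-quartile scaling 635 and 523. Cd69, an early activation antigen, went from 2.23 ± 0.362 to 230 ± 17.0 CPM in Hdac3f/f cells and from 5.45 ± 0.642 to 96.3 ± 10.7 CPM in Lyz2-Cre cells (interaction -2.54 ± 0.20, adjusted p = 1.6e-04). Cd40, the costimulatory receptor, reached 1149 ± 149 CPM in Hdac3f/f and 372 ± 36.6 CPM in Lyz2-Cre cells, from 15.1 ± 0.996 and 17.6 ± 1.08 CPM (-1.84 ± 0.17). In the opposite direction, Itgax rose from 87.1 ± 18.4 to 433 ± 13.5 CPM in Lyz2-Cre cells while its levels were 27.9 ± 3.02 and 35.7 ± 2.02 CPM in Hdac3f/f cells (1.96 ± 0.20).

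The other genes of lowest p had an adjusted p = 3.5e-04, like Cd40 and Itgax. Nod1 (-1.44 ± 0.15) and Nod2 (-1.39 ± 0.13) encode cytosolic sensors of bacterial peptidoglycan, and Nod2 reached 147 ± 4.23 CPM in Hdac3f/f and 92.7 ± 3.06 CPM in Lyz2-Cre cells. Sod2, the mitochondrial superoxide dismutase (-1.39 ± 0.14), Slamf8 (-1.87 ± 0.18), the amino acid transporter gene Slc7a8 (-1.44 ± 0.14), Slco3a1 (-1.93 ± 0.20) and Bcl2a1a, an antiapoptotic gene with close paralogs (-1.76 ± 0.17), also rose less. Lrp4 went from 23.2 ± 1.40 to 34.3 ± 3.02 CPM in Hdac3f/f and from 20.1 ± 0.668 to 10.9 ± 0.322 CPM in Lyz2-Cre cells (-1.45 ± 0.15). St8sia4, a polysialyltransferase, went from 38.0 ± 3.66 to 9.51 ± 1.49 CPM in Hdac3f/f cells and from 32.2 ± 1.84 to 28.5 ± 2.04 CPM in Lyz2-Cre cells (1.82 ± 0.18). These 12 genes stayed called in the same direction in 26 of 26 other settings. Those settings refit the same libraries from which the genes were picked by lowest p, so they are not independent support.

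Interferon response genes had the lowest adjusted p of the lists. Of 30, 21 responded less in Lyz2-Cre cells and none more, or 28 adjusted over the list alone (median -1.28, adjusted p = 7.8e-22; adjusted p = 0.147 with an estimated correlation), with Rsad2 (-2.40), Cmpk2 (-2.26), Oasl1 (-2.07) and Usp18 (-1.42). Rsad2 was higher in Lyz2-Cre cells without LPS, at 189 ± 10.2 against 86.0 ± 25.3 CPM, and lower with it, at 1263 ± 247 against 3026 ± 446 CPM. Of the 18 antigen presentation genes 10 were called, all negative, or 14 adjusted over the list alone (median -1.0, adjusted p = 4.9e-11; adjusted p = 0.147 with an estimated correlation), with Ciita (-2.32), Cd40, Tap2 (-1.25) and Tap1 (-1.12). Of the 22 cytokine genes 8 were called, all negative, or 9 adjusted over the list alone (median -1.02, adjusted p = 3.2e-06; adjusted p = 0.147 with an estimated correlation), with Nos2 (-2.96), Il27 (-2.92), Ccl22 (-2.21) and Ccl7 (-1.77). Il27 reached 296 ± 64.9 CPM in Hdac3f/f and 86.1 ± 10.6 CPM in Lyz2-Cre cells.

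Of the 21 NF-kB feedback genes 8 responded less, or 14 less and 1 more adjusted over the list alone (median -0.62, adjusted p = 3.2e-07; adjusted p = 0.147 with an estimated correlation), with Dusp2 (-1.27), Traf1 (-1.26), Bcl3 (-1.12) and Nfkbia (-0.87). Of 15 inflammasome genes 4 were negative and 1 positive, or 10 and 1 adjusted over the list alone (median -0.45, adjusted p = 0.00324; adjusted p = 0.227 with an estimated correlation). Il18 (-1.69), the pore-forming Gsdmd (-1.17) and the adaptor Pycard (-0.71) were negative, and Nlrp1b, which fell with LPS in Hdac3f/f cells, was positive (2.51). Of the 25 proliferation genes 8 were positive, or 15 adjusted over the list alone (median 0.72, adjusted p = 3.9e-08; adjusted p = 0.155 with an estimated correlation), with E2f1 (1.07), Tk1 (0.99) and Mcm3 (0.72). Tk1 fell with LPS from 16.7 ± 3.27 to 6.43 ± 0.508 CPM in Hdac3f/f cells, and its levels in Lyz2-Cre cells were 7.56 ± 0.701 and 5.77 ± 0.336 CPM.

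The same lean was seen over all LPS-regulated genes, sorted by their mean response in both genotypes. Of 1989 induced genes 444 responded less in Lyz2-Cre cells and 25 more. Their median LPS response was 2.01 in Hdac3f/f and 1.59 in Lyz2-Cre cells on the log2 scale, and the median interaction was -0.44 (camera p = 4.8e-20, and p = 7.6e-05 with an estimated correlation). Of 2644 repressed genes 139 were positive in the interaction and 41 negative (median 0.30, camera p = 2.9e-07, and p = 4.2e-04 with an estimated correlation), with median LPS responses of -1.78 and -1.45. The 139 became 595 with library totals, 302 without Hdac3f/f LPS replicate 1, 42 and 73 without untreated Hdac3f/f replicate 2 and Hdac3f/f LPS replicate 3, and 70, 72, 64, 64 and 87 without untreated Lyz2-Cre replicates 1, 2 and 3 and Lyz2-Cre LPS replicates 1 and 2. For induced genes the median genotype difference was 0.16 without LPS and -0.27 with it, against 0.27 and -0.02 with library totals alone. With a mean response above 2, 245 of 847 induced genes responded less and 10 more (median -0.70). With library totals alone, where the median interaction of all genes moved to 0.27, 219 induced genes responded less and 30 more, and their median was -0.32.

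Over all genes the interaction had a Spearman correlation of -0.263 with GC content. The interaction count also moved when 1 library was left out, which leaves fewer libraries in its group. It was 530 without untreated Hdac3f/f replicate 2 and 1995, with 957 positive and 1038 negative, without Hdac3f/f LPS replicate 1. It was 624, 722, 711, 671, 563 and 686 without Hdac3f/f LPS replicate 3, untreated Lyz2-Cre replicates 1, 2 and 3, and Lyz2-Cre LPS replicates 1 and 2. The count of induced genes with a smaller response was 276, 283 and 270 without untreated Hdac3f/f replicate 2, Hdac3f/f LPS replicate 3 and Lyz2-Cre LPS replicate 1.

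**Figure D4:**
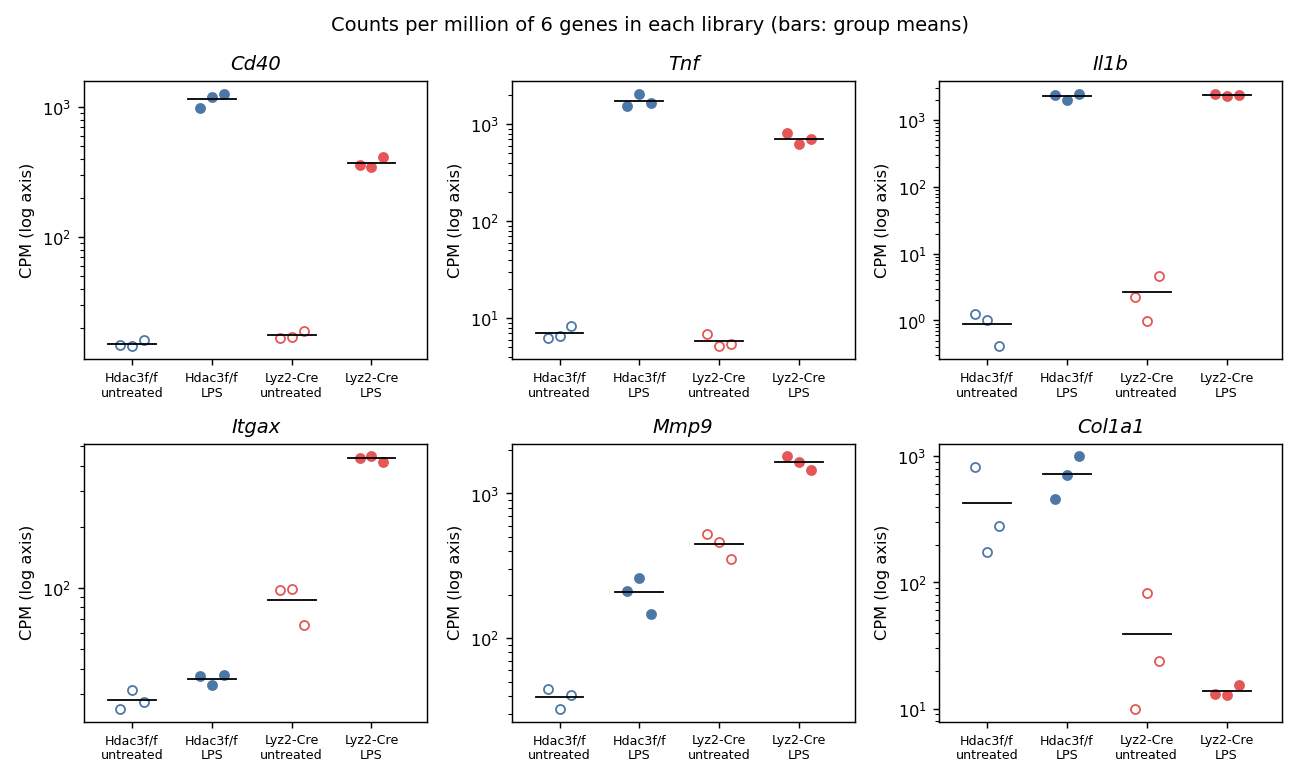
CPM (log axes) of Cd40, Tnf, Il1b, Itgax, Mmp9 and Col1a1; circles are single libraries (open, untreated; filled, LPS; blue, Hdac3f/f; red, Lyz2-Cre-Hdac3f/f) and bars are means of 3 libraries. With LPS, Cd40 reached 1149 CPM in Hdac3f/f and 372 CPM in Lyz2-Cre cells, and Itgax 35.7 and 433 CPM.

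The remaining lists were called in none of the 5 contrasts by camera, and the lowest adjusted p of each follows. It was 0.0683 for neutrophil markers in the untreated genotype comparison, 0.0781 for eicosanoid genes in the genotype comparison with LPS, 0.0890 for HDAC and corepressor subunits in the Hdac3f/f LPS response and 0.120 for dendritic cell markers. It was 0.156 for endoplasmic reticulum stress, 0.203 for p53 targets, 0.223 for alternative activation and for macrophage identity, and 0.327 for oxidative phosphorylation and for osteoclast genes. Of the 11 erythroid markers 3 were tested, too few for a list test. Members of these lists were called all the same. Itgam, which encodes the integrin CD11b, was lower in Lyz2-Cre cells without LPS (48.6 ± 1.41 against 113 ± 7.41 CPM, -1.22 ± 0.12) and with it (74.4 ± 1.5 against 184 ± 35.3 CPM, -1.31 ± 0.12), and Cdh1, an alternative activation gene, was higher (1.64 ± 0.20 and 1.51 ± 0.20). Outside these lists, Pparg, a lipid-sensing nuclear receptor, was at 15.6 ± 2.48 against 41.6 ± 4.11 CPM without LPS (-1.41 ± 0.15). Itgam, Cdh1 and Pparg were chosen after their values were seen.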

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

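The tests of stromal cells and GC bias for genes lower in Lyz2-Cre cells, of GC bias for the smaller LPS induction, and the 3 tests on Lyz2 were chosen only after the results were seen, as were the stromal covariate and the GC and length offsets themselves. For the average response the fit without the library that lacks Lyz2 was not planned either, but its prediction was written before its result. The other groupings of the libraries were planned.

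The response to LPS differed between the genotypes, by the interaction test in edgeR, for 1160 genes. For the 12 genes of lowest p the interaction log2 fold changes were -2.54 for Cd69, -1.84 for Cd40, -1.44 for Slc7a8, -1.87 for Slamf8, -1.39 for Nod2, -1.76 for Bcl2a1a, 1.82 for St8sia4, -1.45 for Lrp4, -1.44 for Nod1, 1.96 for Itgax, -1.39 for Sod2 and -1.93 for Slco3a1. For the lists whose response differed by camera, the median interaction was -1.02 for cytokines, -1.28 for interferon response, -0.62 for NF-kB feedback, -0.45 for inflammasome, 0.72 for proliferation and -1.0 for antigen presentation. None of these 6 calls held with an estimated correlation (adjusted p from 0.147 to 0.227 with an estimated correlation). For genes induced by LPS on average it was -0.44, and for repressed genes 0.30. In 100 drawn groupings of the genotypes within treatments, 4 gave as many interaction genes, the real one included, a share under 0.05. The real count was 1160 and the highest other was 2964. The other 3 (2599, 2964 and 1294 genes) kept all 6 libraries of 1 treatment in their own genotype and only 2 of the other treatment's. The genotype difference enters such a contrast by construction, so these groupings are not draws without an effect. The share of 4 in 100 is therefore not a share expected by chance, and how much of these counts the genotype difference made was not tested. For induced genes called in 1 direction, a smaller response in the real grouping, only 1 of 100 groupings, the real one, reached 444, a share under 0.05. The highest other gave 379, in a grouping that kept all 6 LPS libraries but only 2 untreated ones in their own genotype. Groupings that mix the genotypes also change the spread within groups, so this share does not exclude chance.

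A smaller LPS induction in Lyz2-Cre libraries is the first pattern weighed. With GC and length offsets 624 induced genes responded less and 36 more, which argues against GC and length bias as the whole cause. Without the untreated library that lacks Lyz2 the median interaction of induced genes was -0.41, so that library does not account for the pattern. With the stromal score as a covariate that median was -0.44. The covariate cannot exclude stromal cells, as the score differs between the genotypes. A biological difference, the genotype, stays open and untested as the cause: a candidate explanation is that macrophages of this genotype respond less or more slowly, which a single time point at 4 h cannot separate. How much of the pattern is an untreated difference and how much a deficit with LPS depends on the scale: the median genotype difference of induced genes was 0.16 without and -0.27 with LPS, and 0.27 and -0.02 with library totals.

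The second pattern is the set of 169 genes that were lower in Lyz2-Cre cells in both genotype comparisons by more than 2 on the log2 scale, of which 161 (95.3%) stayed lower in both with GC and length offsets, which argues against that bias as the whole cause. In the untreated Hdac3f/f group a single library, replicate 1, was the highest for 89.9% of the 169 genes, against 42.6% of all tested genes, which is consistent with unequal amounts of stromal cells among the cultures. The most abundant stromal gene, Col1a1, had 429 ± 352 CPM in untreated and 726 ± 270 CPM in LPS-treated Hdac3f/f cells. In Lyz2-Cre cells it had 38.7 ± 38.4 and 13.7 ± 1.41 CPM. Of the 12 tested markers 6 were called lower without LPS, 1 (Pecam1) was called higher and 5 were not called. Among those 5, Cdh5 was at 19.8 ± 15.8 CPM in untreated Lyz2-Cre and 7.93 ± 10.8 CPM in untreated Hdac3f/f cells. With the stromal score as a covariate 30 of the 169 stayed called in both, which decides little, as the score holds genes of the pattern and differs between the genotypes. Some genes did not follow replicate 1, such as Ccnd1 (46.5, 71.0 and 81.5 CPM in the untreated Hdac3f/f libraries) and Cd300ld5 (7.94, 17.2 and 51.4 CPM), both chosen after their values were seen, so stromal cells do not account for the whole set, and whether the genotype changes the number of such cells or these genes in macrophages is open.

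The third pattern is the near absence of Lyz2 from untreated Lyz2-Cre replicate 1, at 0.295% of the Hdac3f/f mean, where single Hdac3f/f libraries held 88.8% to 114% of their group's mean. Of the 7 genes of largest rise between genotypes with LPS, 5 lay above 2 times the highest untreated Hdac3f/f library in it (Gdpd3 at 48.2 against 2.30 CPM, Mmp9 at 523 against 44.5 CPM), 6 in each of the other untreated Lyz2-Cre libraries, and none in single Hdac3f/f libraries against the other two, which argues against an Hdac3f/f culture under a wrong label. That test was written after values of these genes were seen and is the third form: the second used the Lyz2 level, which is the pattern itself, and the first was undecided, with 83.5% of 660 genes higher in Lyz2-Cre cells with LPS above the untreated Hdac3f/f mean in this library, 87.7% and 82.7% in the other untreated Lyz2-Cre libraries, and 22.6% to 75.8% above the mean of the other two in single Hdac3f/f libraries. St6galnac1 and BC018473 had 0 counts as in the other untreated Lyz2-Cre libraries, but Gm11127 (0.0486 CPM), H2-D1 (7128 CPM) and H2-K1 (7594 CPM) lay in the range of the untreated Hdac3f/f libraries, and the Lyz1 count was 872, against 739 and 1295 in the other untreated Lyz2-Cre libraries and 114261 missing Lyz2 reads, so the reads were not counted for Lyz1 instead. The other 5 Lyz2-Cre libraries held on average 55.9% of the Hdac3f/f level, and a candidate explanation is that Cre disrupts Lyz2 on 1 allele in those and on 2 in this library; the allele itself is not read, so this stays open.

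For the 2-group comparisons the 10 groupings of 6 libraries are too few for a share under 0.05. The real one (1 of 10 in each) called 8584 genes for LPS in Hdac3f/f cells, with 0 as the highest other, and 7564 for LPS in Lyz2-Cre cells, with 3 as the highest other. It called 1684 between genotypes without LPS, with 86 as the highest other, and 4656 with LPS, with 0 as the highest other.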

How the results depend on the processing

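The GC and length offsets, the stromal score covariate, the fit without 2 doubted libraries, and for the average response the library totals and the fits without single libraries, were chosen after seeing the data; the other settings were planned.

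Depth of 16553432 to 18706990 counts and 3 libraries per group set the limits: on simulated data no gene with a 1.5-fold interaction was called (0%), and 42.0% with a 2-fold one. A tally of values under another setting covered single genes, lists and counts of LPS-regulated genes by direction of the interaction. Of these values 12972 kept direction and side of the threshold or, for counts, stayed within 1.5 times. Another 961 kept the direction but lost the call, and 3 reversed. The 24 that moved were all counts. Total counts of called genes not given here lay within 1.5 times the reported ones, but the balance of rises and falls moved further in several settings. In the interaction it was 369 positive and 791 negative, and 1134 and 448 with library totals; the positive ones numbered 589 with DESeq2 and 957 without Hdac3f/f LPS replicate 1. Repressed genes positive in the interaction ran from 42 to 302 without 1 library, against 139, and were 595 with library totals. The genes called with a threshold of 1 on the log2 scale added numbered 5051 (LPS in Hdac3f/f), 3938 (LPS in Lyz2-Cre), 794 (genotype, untreated), 1490 (genotype with LPS) and 555 (interaction), and at an adjusted p under 0.01 they numbered 506 (genotype, untreated), 2198 (genotype with LPS) and 371 (interaction), fewer by construction. DESeq2 called 1752 genes in the interaction; the cause was not tested. With the stromal score covariate 1330 genes were called between genotypes with LPS, where the score itself differs between the genotypes. Of induced genes 245 responded less with a mean response above 2, which keeps fewer genes, and 219 with library totals, which shift the scale. Camera with an estimated correlation called 4 lists and fry 77, against 43; fry tests each list by itself and not against other genes. Hdac3 with LPS was 0.17 with library totals, from the shift of the scale.

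Without 1 library, the called genes ran from 7823 to 8750 (LPS in Hdac3f/f), 6583 to 8003 (LPS in Lyz2-Cre), 779 to 2530 (genotype, untreated), 2798 to 6004 (genotype with LPS) and 530 to 1995 (interaction), the induced genes with a smaller response from 270 to 518, and the called lists from 42 to 50. Reversed were the stromal list with LPS (median -0.45, stromal covariate, which is made of the same genes), Chac1 between genotypes with LPS (0.20, stromal covariate; the cause was not tested) and Prss34 in the Hdac3f/f LPS response (-0.0050, library totals, from the shift of the scale). Without both doubted libraries, untreated Hdac3f/f replicate 1 and untreated Lyz2-Cre replicate 1, the 5 contrasts called 8399, 7400, 1952, 4906 and 1216 genes, and with GC and length offsets 9019, 8189, 2256, 4363 and 1651. With replicate number as a block they called 8717, 7687, 1886, 4990 and 1196; replicates of the same number correlated above 0.1 in 5 of 18 pairs and matched best in 14 of 36 tests, so the numbers do not show a pairing. Not run were a pseudocount and a filter meant for a table without counts, and the 2-group fit for the interaction, which needs all 4 groups.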

Other observations

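All genes named in this part except St6galnac2, Cd300ld5, Col1a1 and Hdac3, and its test of chromosome windows, were chosen only after their values were seen.

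Ccnd1, which encodes cyclin D1 and is induced by M-CSF, was lower in Lyz2-Cre cells in each treatment: 8.61 ± 1.90 against 66.3 ± 17.9 CPM without LPS (log2 fold change -2.94 ± 0.24) and 1.80 ± 0.640 against 8.60 ± 1.18 CPM with LPS (-2.26 ± 0.29). The untreated Hdac3f/f libraries held 46.5, 71.0 and 81.5 CPM and the untreated Lyz2-Cre libraries 6.51, 9.12 and 10.2 CPM. The heat shock genes Hspa1a and Hspa1b rose with LPS to 74.8 ± 18.6 and 80.9 ± 19.4 CPM in Hdac3f/f cells and were at 8.65 ± 1.60 and 10.2 ± 3.43 CPM in Lyz2-Cre cells with LPS, with interactions of -2.40 ± 0.30 and -2.45 ± 0.40. Ccl5, a T cell chemokine gene, had an interaction of -2.55 and went from 149 to 2214 CPM in Hdac3f/f and from 306 to 774 CPM in Lyz2-Cre cells. Scd1, the stearoyl-CoA desaturase, was lower in Lyz2-Cre cells without LPS (0.340 ± 0.208 against 3.89 ± 2.84 CPM, -3.47 ± 0.60). It belongs to the 169 genes lower in both genotype comparisons and was highest in Hdac3f/f replicate 1 (7.16, 2.0 and 2.51 CPM).

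Endothelial genes differed between replicates and, like Col1a1, were highest in replicate 1 of the untreated Hdac3f/f libraries and lowest in replicate 1 of the untreated Lyz2-Cre libraries (Col1a1 830.8, 173.5 and 282.7 CPM, and 9.91, 82.3 and 24.0 CPM). Cdh5, which encodes VE-cadherin, was at 20.4, 2.24 and 1.18 CPM in the untreated Hdac3f/f libraries and at 2.14, 32.4 and 24.8 CPM in the untreated Lyz2-Cre libraries. Emcn was at 6.33, 0.730 and 0.153 CPM and at 0.389, 13.1 and 11.1 CPM in the same libraries, and Sox18 at 5.68, 1.12 and 0.767 CPM and at 0.389, 12 and 8.31 CPM. None of the 3 genes was called between genotypes. Gapdh, an abundant housekeeping gene with many pseudogenes, had 5.23 ± 0.155 and 81.3 ± 103 CPM in Hdac3f/f cells without and with LPS and 33.7 ± 49.8 and 70.2 ± 92.0 CPM in Lyz2-Cre cells. These levels are low for this gene, and how reads shared with pseudogenes were assigned is not stated. They are therefore not read as its expression, although Gapdh is a tested member of the glycolysis and hypoxia list and enters its results.

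Some genes were present in 1 genotype alone or nearly so. St6galnac1 had 14 to 26 counts in each Hdac3f/f library and 0 counts in all 6 Lyz2-Cre libraries, which allows up to 3 counts in each, and BC018473 had 71 to 435 counts in Hdac3f/f libraries, 0 in 5 Lyz2-Cre libraries and 1 in the sixth. Both lie on chromosome 11 near St6galnac2, Cd300ld5, Cygb and Gm11735. Of 192 genes that changed more than 4-fold alike in both genotype comparisons, these 6 lay in 1 window of 2 Mb that starts at 115031486. The highest number in 1000 random draws of as many tested genes had a median of 4 and a 95th percentile of 5. Of the draws 37 held 6 or more. A window on chromosome 17 that starts at 34143307 held 4 such genes, Gm11127 among them, which equals the median of the draws. A hypothesis is that sequence around the chromosome 11 window differs between the genotypes apart from the Hdac3 and Lyz2 loci. The value of 6 would go with linked variants, but tissue genes with shared regulation could lie together too, and no genotype was read. Gm11127, on chromosome 17, was at 0 to 0.205 CPM in Hdac3f/f libraries, at 0.0486 CPM in untreated Lyz2-Cre replicate 1, and at 7.43 to 16.0 CPM in the other 5 Lyz2-Cre libraries, so this library differs from the others of its genotype at Lyz2 and at Gm11127. It also differs from the other untreated Lyz2-Cre libraries at H2-D1 (7128 against 3637 and 3988 CPM) and H2-K1 (7594 against 4681 and 5258 CPM), which lie on chromosome 17 too, and is there in the range of the untreated Hdac3f/f libraries.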
